A study of Homo sapiens with 6 samples.

How the data were processed

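The samples were 6 RNA preparations from human monocyte-derived macrophages, 3 mock-treated controls and 3 treated with IFNalpha for 4 h. Per the labels, monocytes were plated in medium, serum was added after some hours and the cells differentiated for 7 days, and biotin-labelled cRNA was made from 30 ng of total RNA. The labels name donors 1 to 3 in both groups, so replicates are cells of separate donors and each donor gave both treatments. The dose of IFNalpha is not given in the sources used here.

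The deposited values were MAS5 signals, per the submitters' processing notes. MAS5 estimates 1 linear intensity per probe set from its matched and mismatched probes and scales each array to a target; its version and settings are not given in the sources used here. In the deposited intensity values the mean between the 2% and 98% ends of each array was 499.9, so they were already scaled to one level and were used without further normalization. Detection calls were not used here, so a dim gene was not told apart from background by the array's own call.

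Probe sets were named with the platform annotation and current symbols by gene identifier, of which 99.9% matched (RefSeq annotation of GRCh38.p14, used for names only). Of 54675 probe sets, 41030 had one gene, 1765 had several and 11721 were not listed and are unnamed here. Left out of every step were 62 control probe sets, except as quality measures, and 97 probe sets of sex-linked transcripts. For each of 19739 genes the probe set with the highest mean log2 value over the 6 arrays was used. Of the 958 genes later called, 549 had another tested probe set. For 276 of them another one passed the same way, for 273 no other passed, and in no gene did another pass in the opposite direction. Some probe sets share sequence between related genes (HLA, metallothionein and interferon alpha genes among them), so such genes are uncertain one by one.

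Values were put on the log2(signal + pseudocount) scale with a pseudocount of 18.6, the 25th percentile of all signals. Genes with a signal above 75.1, the pooled median, in at least 3 of 6 arrays were kept, which left 12627. IFNalpha was compared with control in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All adjusted p of single genes are from this limma fit unless another is named. The main fit had no donor term, and the fit with the donor as a block was the alternative. The SE given are from the fit without a donor term, so they include the spread between donors and do not measure the precision of the change within donors. Pairing was checked by the deviations from the group means across genes. Arrays of the same donor correlated at 0.286, 0.242 and 0.300, and arrays of different donors between −0.236 and −0.059, so the donor numbers pair the arrays. Blocked values are given where they change a call or move a count by more than 1.5 times. A step with no single fit, the spread between donors, is given as values, because 1 array per donor and treatment allows no test of whether donors differ in response.

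Gene lists (31 lists, 764 genes) and the rule for named genes were written before the data were examined. Named were the 12 largest increases and 8 largest decreases among genes past the threshold that moved one way in all 3 donors; from each list up to 4 members past the threshold with the lowest p or, where fewer than 2 passed, the 2 brightest; and a short set of interferon-response and control genes. Any other gene named was chosen after its value was seen. Lists were tested with limma's camera (preset correlation 0.01, and with an estimated correlation) and fry, each adjusted over the 31 lists. Quality measures were compared with exact two-sided permutation tests, which cannot go below p = 0.1 with 3 arrays against 3.

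The fit was tested on simulated data for the 12627 genes. They used the control means, variances drawn from the prior distribution that the fit estimated, and independent normal noise. Of 100 genes changed by log2 2, 60% were recovered, and of 130 changed by log2 1, 22.3% were, with mean estimates of 1.96 and 0.97 and 1 false call among 90. The simulated data had no donor effect and no correlation between genes, and fewer changed genes than were called in the real data. The shares recovered and falsely called therefore need not hold for the real data. Alternatives were the pseudocount, the filter, quantile normalization, median centring, the variance model, the choice of probe set, the donor block alone and with either normalization, and leaving out each array and each donor. The block with median centring was added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Of the gene families tested after the data were seen, 1 is not reported here.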

Results

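RNA was measured in human macrophages grown from blood monocytes for 7 days and then either mock-treated or given interferon alpha (IFNalpha), an antiviral cytokine, for 4 h. Cells of 3 donors were used, and each donor gave 1 array per treatment, so that 3 control arrays stood against 3 IFNalpha arrays. The arrays were whole-transcriptome oligonucleotide arrays with 54675 probe sets, each read out as a MAS5 signal, a linear brightness that combines the probes of a set. All arrays had been scaled to one level, with a trimmed mean of 499.9 on each, and their median signals lay between 64.1 and 85.0. Of 19739 genes with a probe set of their own, 12627 were bright enough to test. The number of arrays limits the precision, and all changes are given as log2 IFNalpha minus control on the log2(signal + 18.6) scale with the standard error of the fit (SE, n = 3 per group), which understates the change of dim genes. Signals are given as mean ± SD over 3 arrays.

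The comparison asked which transcripts changed within 4 h of IFNalpha. The largest increases were a mixture of inflammatory, metabolic and antiviral genes. Their order is uncertain, since of the 12 only TNFAIP6, CCL20 and RSAD2 had control means above the pooled median signal. The change of the others depends on the pseudocount, with control means as low as 16.6 (EBI3) and 18.4 (ACOD1). Over the other settings the change was 5.51 to 8.07 for EBI3, 6.00 to 8.29 for ACOD1 and 3.75 to 6.62 for DNAAF1. It was 7.24 to 8.16 for TNFAIP6 and 6.27 to 6.80 for RSAD2. TNFAIP6, which encodes a secreted hyaluronan-binding protein, rose by 7.74 ± 0.38, from a signal of 173 ± 108 to 36284 ± 5320. ACOD1, which makes itaconate, rose by 7.34 ± 0.56, and IDO1, which starts the breakdown of tryptophan, by 7.23 ± 0.53. They were followed by TNIP3 (7.09 ± 0.35), an inhibitor of NF-kB signalling, by CCL20 (7.03 ± 0.60) and CXCL11 (6.93 ± 0.45), both chemokines, and by the cytokine subunit gene EBI3 (6.92 ± 0.31). RSAD2, which encodes the antiviral enzyme viperin, rose by 6.58 ± 0.22, and LAMP3, a marker of mature dendritic cells, by 6.47 ± 0.34. The last of the 12 largest increases were IL6 (6.21 ± 0.52), DNAAF1 (6.17 ± 0.29), a dynein assembly factor of cilia, and ISG20 (6.14 ± 0.30), an RNA exonuclease. The largest decreases were in transcription factors of the immediate early class. FOSB fell by 4.21 ± 0.48, EGR3 by 4.21 ± 0.29 and EGR1 by 4.04 ± 0.24, and the EGR1 signal went from 14812 ± 2320 to 908 ± 274. NR4A2 (−3.51 ± 0.43), ZNF331 (−3.47 ± 0.42) and FOS (−3.31 ± 0.56) fell too, as did RGS2 (−3.39 ± 0.49), which restrains G protein signalling, and CACNA2D3 (−3.32 ± 0.52), a calcium channel subunit. These 20 genes had adjusted p between 5.74e-07 (RSAD2) and 0.00637 (FOS) in limma. Without donor 2 the adjusted p was 0.0637 for FOS, 0.0681 for RGS2 and 0.0815 for CACNA2D3.

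**Figure D1:**
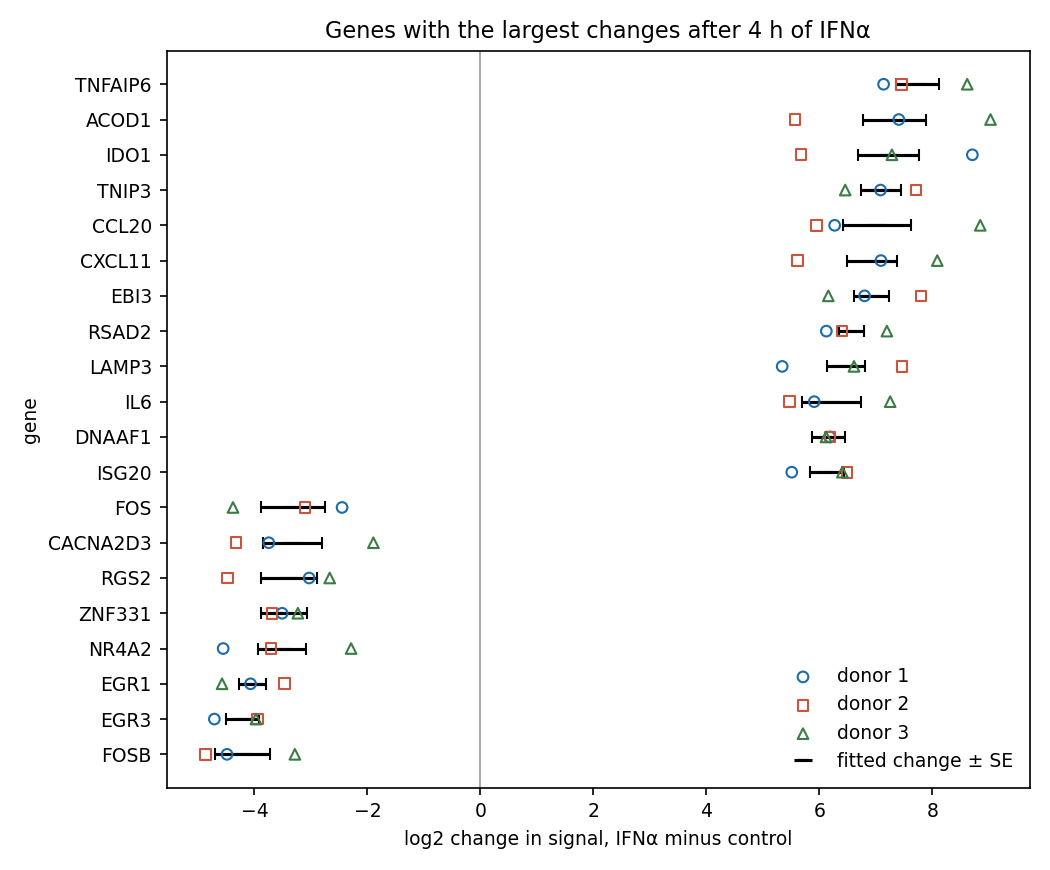
The 12 genes with the largest increase and the 8 with the largest decrease, with the log2 change in signal on the horizontal axis and the gene on the vertical axis. Open symbols are the IFNalpha minus control values of the 3 donors and bars the fitted change ± SE. The 3 donors lie on the same side of 0 for every gene shown, because the genes were chosen by that rule.

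In all, 585 genes were higher and 373 lower in the IFNalpha arrays (limma, adjusted p under 0.05), and all 958 had moved the same way in the 3 donors. Increases were larger than decreases: 216 genes rose at least 4-fold and 23 fell at least 4-fold, and the median change was 1.55 among the higher and −1.04 among the lower genes. Between donors, the changes of all tested genes correlated across genes with r of 0.56, 0.53 and 0.58, and those of the 958 genes with r of 0.95, 0.93 and 0.93. Genes are not independent replicates. The 958 were called on these same arrays, so their shared direction and higher r follow at least in part from that selection. With the donor as a block, 889 genes were higher and 1098 lower, and these included all 958. The split between higher and lower depended on the scaling, since the median change of all tested genes was −0.12 on the deposited scale and −0.01 after each array was centred on its median, which gave 682 higher and 249 lower genes (73.3% higher against 61.1%). The count of lower genes also depended on single arrays and donors. It was 197, 181 and 244 without control array 1, 2 and 3, 244 and 195 without IFNalpha array 1 and 2, and 99, 54 and 243 without donor 1, 2 and 3; that of higher genes was 340 without donor 1 and 280 without donor 2. The 3'/5' signal ratios of the array's control transcripts, a sign of RNA integrity, were 1.42 ± 0.07 and 1.55 ± 0.07 for GAPDH and 4.01 ± 0.61 and 4.51 ± 0.22 for ACTB in control and IFNalpha arrays. Their exact two-sided permutation p were 0.2 and 0.3. Hybridization spikes read 4843 ± 1336 and 6377 ± 181 (exact permutation p = 0.1, the smallest that 3 arrays against 3 can give).

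**Figure D2:**
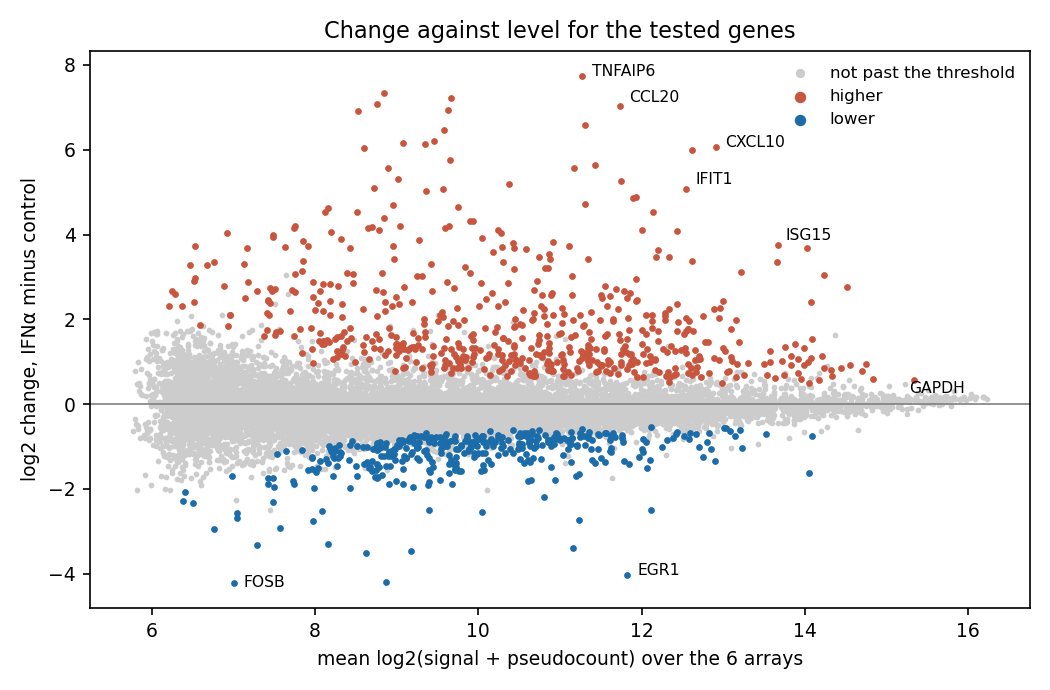
Change against level for the 12627 tested genes, with the mean log2(signal + pseudocount) of the 6 arrays on the horizontal axis and the log2 change, IFNalpha minus control, on the vertical axis. Red points are the 585 genes that were higher, blue points the 373 that were lower and grey points the others; increases reach 7.74 (TNFAIP6) and decreases −4.21 (FOSB).

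The genes were also read as 31 lists fixed before the data were examined. Of these, 18 passed limma's camera test with a preset correlation of 0.01, 7 of them also with an estimated correlation, and with both the donor block and an estimated correlation the adjusted p of these 7 was 0.155 each. Each of the 7 also lost that call without any 1 donor, without control array 3 and without IFNalpha array 3 (adjusted p between 0.0558 and 0.182), as did 6 of them without IFNalpha array 1, 3 without control array 2 and 1, the chemokines, without control array 1 or IFNalpha array 2. The test with an estimated correlation has fewer degrees of freedom with the block or with arrays left out. Calls lost in those settings, and the blocked values of that test given below, therefore cannot tell a weaker rise from lower power. The filter alone also ended calls of that test, with all 6 arrays and no block. With the filter at the 70th percentile 2 of the 7 lists lost the call (adjusted p = 0.0507), and with the filter on the mean level 1 did (0.0619). The 7 were the lists of HIV-1 restriction factors, negative regulators of cytokine signalling, ISG15 and ubiquitin conjugation, chemokines, inflammatory cytokines, apoptosis, and tryptophan and small-molecule metabolism. Fry asks whether members move one way on balance, not whether they move more than other genes. With the donor block it gave these 7 lists adjusted p between 0.00991 and 0.0116, all upward. Estimated correlations ran from −0.04 for B cell markers to 0.71 for ribosomal proteins, with 0.52 for antiviral effectors, against the preset 0.01. With the preset correlation camera takes its degrees of freedom from the number of genes. Its very small p therefore do not measure the spread between 3 arrays per group. The counts of members are given before the set tests. Counts adjusted over all 12627 genes are followed by those adjusted over the list alone.

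**Figure D3:**
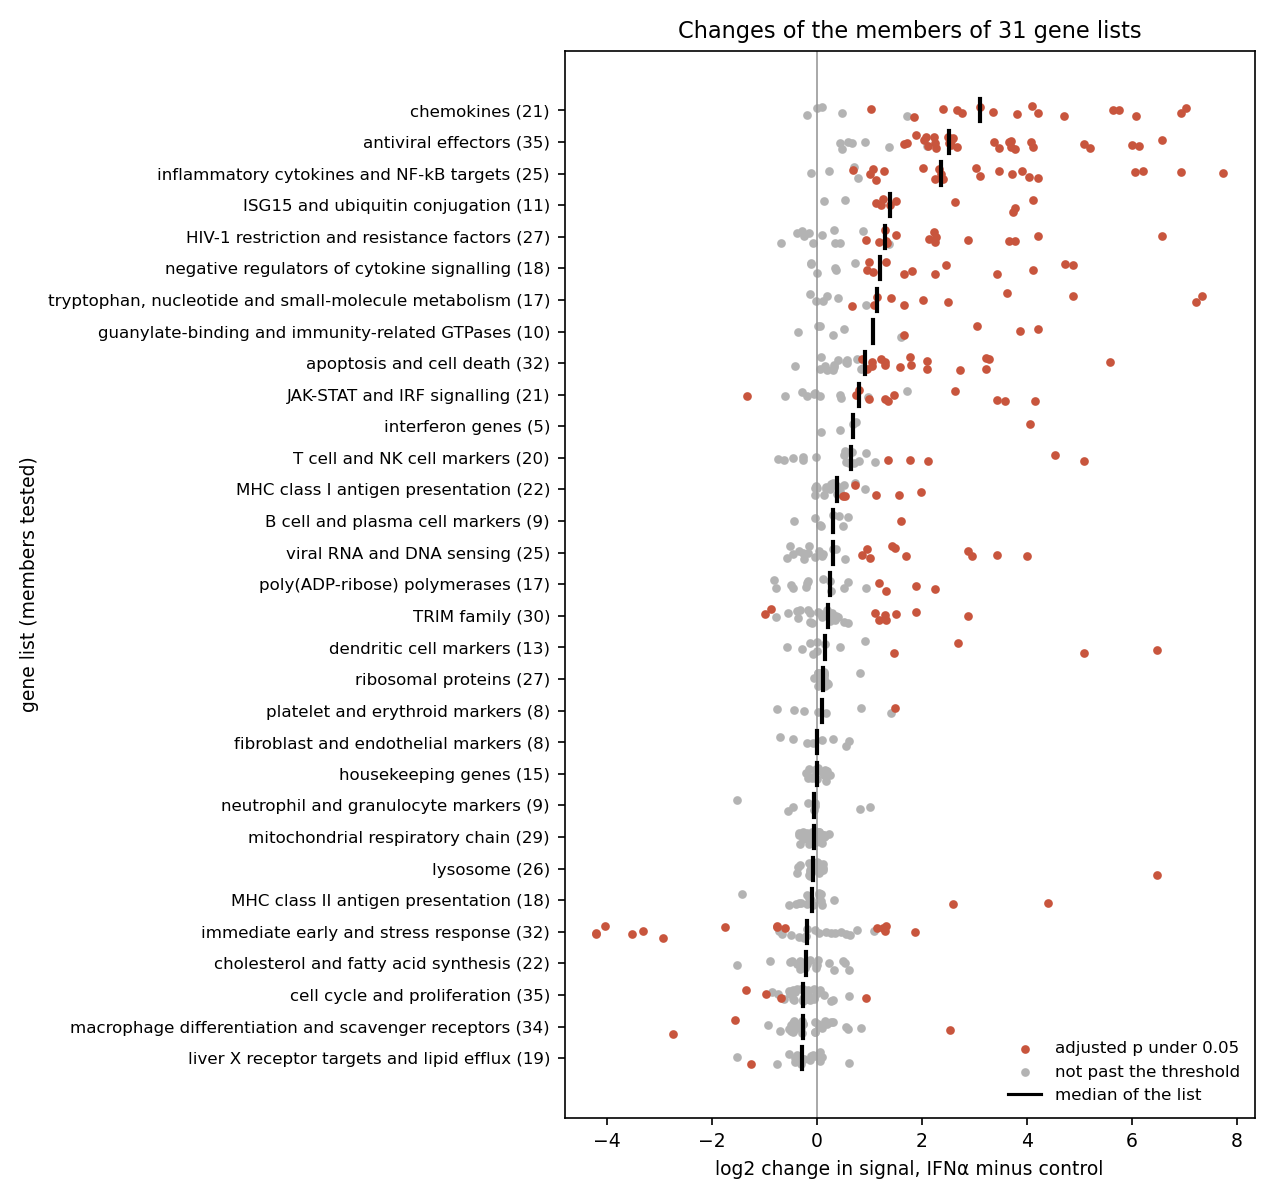
Log2 change in signal, IFNalpha minus control, of the members of the 31 lists, with 1 row per list and the number of members tested in brackets. Red points passed the adjusted threshold, grey points did not, and the black bar is the median of the list; medians run from 3.10 for chemokines to −0.29 for liver X receptor targets.

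Antiviral genes rose broadly. Of 35 tested antiviral effectors, 28 were higher (32 adjusted over the list alone), with a median change of 2.52. Besides RSAD2 and ISG20, CMPK2, a nucleotide kinase, rose by 4.08 ± 0.21 and RTP4 by 3.46 ± 0.18. IFIT1, which binds viral RNA, went from 1160 ± 734 to 35021 ± 5946 and ISG15, a ubiquitin-like modifier, from 3770 ± 1680 to 48066 ± 5370. MX1, a GTPase that blocks several viruses, rose by 3.36 ± 0.53 (limma adjusted p = 0.00437, but 0.0770 without donor 2). OAS1, which makes an activator of RNA decay, changed by 2.10 ± 0.76 (adjusted p = 0.145) and BST2, which tethers budding virions, by 0.44 ± 0.22 (adjusted p = 0.304); with the donor block their adjusted p were 1.60e-05 and 0.0461. OAS1 also passed without control array 1 (0.0187), without donor 1 (0.00273) and as the mean of its probe sets (0.0434). The list had an adjusted p of 1.53e-46 in camera and 0.0600 with an estimated correlation. Of 27 factors known to restrict or resist HIV-1, 15 rose (16 adjusted over the list alone), with a median of 1.30 and an adjusted p of 0.0411 with an estimated correlation (0.155 with the donor block). They shared 8 tested members with the antiviral effectors. ZC3HAV1, which targets viral RNA, rose by 2.25 ± 0.16 and GBP5, which impairs envelope maturation, by 4.21 ± 0.34. Of these 27, 9 were called when probe sets that can share sequence were left out. T cell and NK cell markers, described further on, moved on the same arrays, with 5 of 20 higher, and 2 or 3 without any 1 donor or without IFNalpha array 1 or 3.

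Most genes of ISG15 conjugation and some antiviral GTPases and poly(ADP-ribose) polymerases rose. In the list of ISG15 and ubiquitin conjugation, 9 of 11 rose (10 adjusted over the list alone; adjusted p = 0.0158 with an estimated correlation, 0.155 with the donor block). HERC5, the ligase for ISG15, rose by 3.72 ± 0.17, HERC6 by 2.62 ± 0.21 and USP18, which removes ISG15 and dampens interferon receptor signalling, by 4.11 ± 0.19. Among guanylate-binding and immunity-related GTPases, 4 of 10 rose (5 adjusted over the list alone), and 6 did with the donor block. GBP4 rose by 3.86 ± 0.21, GBP2 by 1.65 ± 0.22 and GBP1, already bright at 6845 ± 1758, to 56118 ± 12044; the camera adjusted p was 6.70e-07, and 0.0600 with an estimated correlation. Of 17 poly(ADP-ribose) polymerases, 4 rose, also adjusted over the list alone, where 1 more fell, as 1 did with the donor block and without IFNalpha array 1 (camera adjusted p = 0.00740; adjusted p = 0.0868 with an estimated correlation and 0.0943 when probe sets that can share sequence were left out). They were ZC3HAV1, PARP14 (1.88 ± 0.24), PARP12 (1.18 ± 0.15) and PARP9 (1.31 ± 0.19), the last with an adjusted p of 0.286 and a change of 0.45 when probe sets that can share sequence were left out. In the TRIM family, 7 of 30 rose and 2 fell (8 and 2 adjusted over the list alone), with an adjusted p of 0.00448 in camera and 0.0723 with an estimated correlation. This list shared 5 tested members with the HIV-1 restriction factors (PML, TRIM25, TRIM22, TRIM21 and TRIM5). All 5 were higher, so the 2 lists are not separate evidence. PML, the organizer of nuclear bodies, rose by 2.87 ± 0.27, TRIM56 by 1.88 ± 0.26 and TRIM25, which modifies the RNA sensor RIG-I, by 1.50 ± 0.20. TRIM8 fell by 1.00 ± 0.15, with an adjusted p of 0.0773 without donor 2 and 0.211 for the mean of its probe sets. Without donor 1, 4 TRIM genes rose, and 0 fell without donor 2 and 1 without any other donor or array.

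Sensors of viral nucleic acid rose in part, and genes on both sides of interferon signalling changed. Of 25 sensing genes, 10 rose (10 adjusted over the list alone, where 1 fell, as 1 did with the donor block), with a median of 0.30, a camera adjusted p of 3.65e-06 and an adjusted p of 0.0600 with an estimated correlation. The cytosolic RNA sensors IFIH1 and RIGI rose by 2.95 ± 0.17 and 3.42 ± 0.33, DHX58, their relative, by 3.99 ± 0.48 and the adaptor MYD88 by 1.01 ± 0.12. In the list of JAK-STAT and IRF signalling, 10 of 21 rose and 1 fell (13 and 2 adjusted over the list alone), with an adjusted p of 2.39e-08 in camera and 0.115 with an estimated correlation. STAT4 rose by 3.58 ± 0.22, BATF2 by 4.15 ± 0.26, and the interferon regulatory factors IRF1 and IRF7 by 3.43 ± 0.28 and 2.63 ± 0.23. The member that fell, named after its value was seen, was IFNGR1, a chain of the interferon gamma receptor, by 1.33 ± 0.14; with the donor block 2 members fell. IRF9, the DNA-binding part of the type I interferon transcription complex, changed by 0.96 ± 0.29 (limma adjusted p = 0.0856, but 0.00765 with the donor block and 0.0485 after median centring). The receptor chains IFNAR1 and IFNAR2 changed by −0.28 ± 0.16 and −0.20 ± 0.19 and did not pass. Of 18 negative regulators of cytokine signalling, 12 rose (13 adjusted over the list alone; adjusted p = 0.0158 with an estimated correlation, 0.155 with the donor block). SOCS3 and SOCS1, feedback inhibitors of JAK kinases, rose by 4.73 ± 0.36 and 3.42 ± 0.27, and CD274, the ligand PD-L1 that restrains T cells, by 4.87 ± 0.25. Without donor 2, 5 sensing genes and 5 JAK-STAT genes were called as higher, and without donor 1, 5 JAK-STAT genes and 7 negative regulators were. Of 5 tested interferon genes only IFNG rose, by 4.05 ± 0.65 from 11.8 ± 7.0 to 669 ± 689, with an adjusted p of 0.00469 that was 0.0630 without donor 2. IFNA17 (0.74 ± 0.48) and IFNL2 (0.44 ± 0.43) did not pass. This list had a camera adjusted p of 0.0347, and of 0.444 with an estimated correlation, 0.0636 with the donor block, 0.0657 after median centring and between 0.144 and 0.333 without control array 3, IFNalpha array 3 or donor 3; 1 of 5 was also the count adjusted over the list alone.

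Chemokine and inflammatory cytokine transcripts rose beside the antiviral ones. Of 21 chemokines, 16 rose (17 adjusted over the list alone), with a median of 3.10 and an adjusted p of 0.0441 with an estimated correlation (0.155 with the donor block). CXCL10, which draws activated T cells, went from 972 ± 368 to 63690 ± 12239, and CCL5 from 375 ± 69 to 19532 ± 2645. The neutrophil attractant CXCL1 rose by 5.75 ± 0.30. Of 25 inflammatory cytokines and NF-kB targets, 21 rose (23 adjusted over the list alone), with a median of 2.35 and an adjusted p of 0.0158 with an estimated correlation (0.155 with the donor block). Beside TNFAIP6, EBI3 and IL6, the adhesion molecule gene ICAM1 rose by 2.35 ± 0.14 and TNFAIP2 by 3.46 ± 0.23. The donors' medians for this list were 2.07, 2.56 and 2.67. On the same arrays 5 of 20 T cell and NK cell markers rose (2 or 3 without any 1 donor or without IFNalpha array 1 or 3), and the GAPDH 3'/5' ratio was 1.55 ± 0.07 against 1.42 ± 0.07.

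Some genes of the 2 MHC antigen presentation lists rose, while most did not pass. In the MHC class I list, 6 of 22 rose, also adjusted over the list alone, and 10 did with the donor block. They included the peptide transporter gene TAP1 (1.99 ± 0.15), the class I transactivator NLRC5 (1.57 ± 0.19) and the proteasome subunits PSMB9 (1.13 ± 0.16) and PSMA2 (0.72 ± 0.12). PSMA2 had an adjusted p of 0.254 when probe sets that can share sequence were left out, 0.0545 without donor 1 and 0.0905 without donor 2. B2M, the light chain of class I molecules, changed by 0.17 ± 0.10 from 65953 ± 3762 and did not pass. The list had a camera adjusted p of 3.11e-08 and an adjusted p of 0.115 with an estimated correlation, and 3 members were called without donor 1 or donor 2. In the MHC class II list, 2 of 18 rose, and adjusted over the list alone 2 rose and 1 fell. The 2 were CD80 (4.39 ± 0.27) and CD40 (2.58 ± 0.20), which are costimulatory molecules and not class II chains; 2 members fell with the donor block, and 1 without donor 3 or control array 3. The median of this list was −0.09 and its mean 0.22, and its camera adjusted p was 0.423.

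Cell death genes and enzymes of small-molecule metabolism rose as lists. Of 32 apoptosis and cell death genes, 17 rose (20 adjusted over the list alone), with a median of 0.92 and an adjusted p of 0.0158 with an estimated correlation (0.155 with the donor block). TNFSF10, the death ligand TRAIL, went from 327 ± 106 to 16176 ± 3253. APOL3 and APOL6 rose by 3.22 ± 0.25 and 3.21 ± 0.37 and the kinase RIPK2 by 1.78 ± 0.15. Of 17 genes of tryptophan, nucleotide and small-molecule metabolism, 11 rose, also adjusted over the list alone, with a median of 1.14 and an adjusted p of 0.0158 with an estimated correlation (0.155 with the donor block). GCH1, which makes the cofactor tetrahydrobiopterin, went from 703 ± 59 to 21247 ± 2092, and NT5C3A, a nucleotidase, rose by 3.63 ± 0.28. Without donor 2, 6 apoptosis genes and 7 metabolic genes were called, and without donor 1, 11 apoptosis genes were; 7 metabolic genes were called when probe sets that can share sequence were left out.

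The list of immediate early and stress genes moved both ways. Of 32 tested, 10 fell and 5 rose (10 and 8 adjusted over the list alone, and 12 and 8 with the donor block). EGR1, EGR3, FOSB and NR4A2 led the decreases. The camera adjusted p was 0.533, and fry, which tests whether the members move one way on balance, gave an adjusted p of 0.0332, and 0.0662 with the donor block. The number that fell was 6 after median centring, 5 without donor 2 and 6 without donor 1, control array 1 or 2, or IFNalpha array 2. The number that rose was 2 without donor 1 and 3 without control array 1 or 3. Among 35 cell cycle genes, 3 fell and 1 rose (4 and 2 adjusted over the list alone, and 6 and 2 with the donor block), and the adjusted p was 0.210 in camera (0.00185 without control array 1 and 0.0457 with no filter) and 0.460 in fry (0.0374 in fry with the donor block). MYC fell by 1.35 ± 0.27, the replication helicase subunit gene MCM6 by 0.69 ± 0.16 and the mitotic kinase gene AURKA by 0.98 ± 0.25, while CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 0.94 ± 0.13. The 3 decreases depended on single arrays, and those of MCM6 and AURKA also on the processing. MYC had an adjusted p between 0.0517 and 0.167 without control array 1 or 2, IFNalpha array 1 or 2, or donor 1 or 2. MCM6 had one between 0.0625 and 0.263 without control array 2 or 3, any IFNalpha array or any donor, and AURKA one between 0.0938 and 0.267 without the same arrays, donor 2 or donor 3. Median centring (0.0676 and 0.0691), no variance trend (0.0863 and 0.0953) and the mean of probe sets (0.152 and 0.317) also ended the calls of MCM6 and AURKA, and the AURKA change for that mean was −0.53. Quantile normalization (0.0653) and no filter (0.0580) ended that of AURKA. On these arrays the ACTB 3'/5' ratio was 4.51 ± 0.22 with IFNalpha and 4.01 ± 0.61 in control.

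Lipid and macrophage identity genes showed few calls in the unblocked fit and more decreases with the donor block. Of 34 genes of macrophage differentiation and scavenger receptors, 2 fell and 1 rose (3 and 1 adjusted over the list alone); with the donor block 9 fell and 2 rose. CXCR4, a chemokine receptor, fell by 2.74 ± 0.39 and MERTK, a receptor for the uptake of dying cells, by 1.56 ± 0.25, and ADGRE1 rose by 2.53 ± 0.34. Without donor 1 the adjusted p was 0.0547 for CXCR4 and 0.0521 for MERTK, and that of MERTK was 0.0926 for the mean of its probe sets. The camera adjusted p of the list was 0.525. Of 19 liver X receptor targets and lipid efflux genes, 1 fell, also adjusted over the list alone, and 5 did with the donor block; the adjusted p was 0.202 in camera (0.0460 with quantile normalization and 0.0443 with no filter) and 0.0995 in fry, and 0.0359 and 0.00991 with the donor block (0.235 in camera with the block and an estimated correlation). The 1 was PLIN2, which coats lipid droplets (−1.26 ± 0.23; adjusted p 0.0905 without donor 2, 0.0514 with no variance trend and 0.202 for the mean of its probe sets, a change of −0.70). NPC2 and APOC1, the brightest of the list, changed by 0.06 ± 0.13 and 0.06 ± 0.19. Of 22 genes of cholesterol and fatty acid synthesis, 0 passed in limma, also adjusted over the list alone, where 2 higher and 1 lower had an unadjusted p under 0.05, and 2 rose and 2 fell with the donor block; 1 fell without control array 1. SCD changed by −0.01 ± 0.35 and INSIG1, which holds back sterol synthesis, by 0.61 ± 0.19 (adjusted p = 0.10, but 0.0204 with the donor block, 0.0491 after median centring and 0.0197 without control array 2); the camera adjusted p was 0.752 (0.0292 without donor 1).

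Lists that stand for general cell function had few or no members past the threshold. Of 26 lysosomal genes, 1 rose, also adjusted over the list alone, and that was LAMP3; GPNMB and LIPA, the brightest, changed by 0.11 ± 0.11 and 0.12 ± 0.11. LIPA passed only as the mean of its probe sets (1.77, adjusted p = 0.000605), and 1 lysosomal gene fell with the donor block. In limma 0 of 29 respiratory chain genes, 0 of 27 ribosomal protein genes and 0 of 15 housekeeping genes passed, also adjusted over the list alone. At an unadjusted p under 0.05, 1 respiratory chain gene was lower and 1 ribosomal protein gene higher. COX7C changed by 0.04 ± 0.11, COX6A1 by 0.11 ± 0.11, RPS23 by 0.15 ± 0.13, RPS16 by 0.13 ± 0.11, GAPDH by 0.00 ± 0.11 and ACTB by 0.13 ± 0.10. With quantile normalization the signs of GPNMB, LIPA, NPC2, APOC1, COX7C, COX6A1, RPS16, GAPDH and ACTB turned negative, and that of SCD turned positive after median centring. The medians of the lysosomal, respiratory chain, ribosomal and housekeeping lists were −0.07, −0.06, 0.12 and 0.00, and after median centring 0.04, 0.05, 0.23 and 0.11. Camera gave adjusted p of 0.591, 0.924, 0.00448 and 0.327; for the ribosomal list it was 0.660 with an estimated correlation, 0.832 with quantile normalization and between 0.0806 and 0.298 without control array 3, IFNalpha array 1 or donor 1, and for the respiratory chain 0.0272 with quantile normalization.

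Markers of other cell types were read in the same way. Of 20 T cell and NK cell markers, 5 rose, also adjusted over the list alone, with a camera adjusted p of 9.29e-06 and an adjusted p of 0.0868 with an estimated correlation. The number was 2 without donor 1 and 3 without donor 2, donor 3, IFNalpha array 1 or IFNalpha array 3. They were led by IL7R, a cytokine receptor chain (939 ± 217 to 22676 ± 7432), and CCR7, a homing receptor (117 ± 48 to 4726 ± 1994), followed by CD2 (1.35 ± 0.24) and CD8A (2.11 ± 0.41). CD8A lost its call without IFNalpha array 1 (adjusted p = 0.0647), IFNalpha array 3 (0.0569) and donor 1, 2 or 3 (0.126, 0.0559 and 0.0937), and CD2 without donor 1 (0.0609) and donor 2 (0.0952). Of the T cell receptor complex, CD3D changed by 0.79 ± 0.27 and TRBC1 by 0.61 ± 0.29, and neither passed. Of 13 dendritic cell markers, 4 rose, also adjusted over the list alone: LAMP3, CCR7, IRF8 (1.47 ± 0.17) and BATF3 (2.69 ± 0.60). BATF3 had an adjusted p of 0.0240, and between 0.0631 and 0.0938 without donor 1, without any 1 of the 3 IFNalpha arrays, or with no variance trend, and 0.0622 with robust variance; the camera adjusted p of the list was 0.000578 and its adjusted p 0.132 with an estimated correlation. Of 9 B cell markers, 1 rose, also adjusted over the list alone (PAX5, 1.60 ± 0.34), while IGKC and JCHAIN changed by 0.31 ± 0.24 and 0.59 ± 0.50. Leaving out control array 1 or 2, IFNalpha array 1 or 2, or donor 1 or 2 gave PAX5 adjusted p between 0.0531 and 0.216, no filter gave 0.0528, and the mean of its probe sets gave 0.240 with a change of 0.85. Of 8 platelet and erythroid markers, 1 rose, also adjusted over the list alone (GP1BA, 1.48 ± 0.23; adjusted p 0.0610 without donor 1), and ITGB3 and HBB changed by −0.44 ± 0.28 and 0.02 ± 0.31. In limma 0 of 9 neutrophil markers and 0 of 8 fibroblast and endothelial markers passed, also adjusted over the list alone, where 2 neutrophil markers were lower and 1 fibroblast marker higher at an unadjusted p under 0.05, and the latter passed with the donor block. CSF3R and MMP8 changed by −0.17 ± 0.20 and −0.04 ± 0.62, PECAM1 by −0.18 ± 0.23 and ACTA2 by 0.61 ± 0.21 (adjusted p = 0.124, and 0.0338 with the donor block). The sign of MMP8 turned with both other scalings. Camera adjusted p for the B cell, platelet, neutrophil and fibroblast lists were 0.123 (0.0476 with quantile normalization), 0.249, 0.924 and 0.525.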

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

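The tests of donor spread, of lymphocyte share, of handling and of the scaling of single immediate early genes below were chosen after the results they bear on were seen, and the second NF-kB list was written after the first list's result but before its own values.

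Probe sets with no single gene also changed. Of 4452 tested, 87 were higher and 46 lower in the IFNalpha arrays, and 141 and 137 with the donor block. They lie outside the gene comparison, which took only probe sets with one gene. Among those that match several genes 35 of 1095 were higher, and among those not listed 52 of 3357, against 888 of 23026 probe sets with one gene. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05, so the real split is always 1 of 10. It gave 585 higher and 373 lower genes, 133 of these probe sets and 18 lists. The highest of the other splits gave 0 genes and 0 probe sets in limma (747 genes at an unadjusted p under 0.05, against 2668 in the real split). Camera with the preset correlation still passed between 8 and 16 lists in the other splits. Each of these splits sets 2 arrays of one treatment and 1 of the other against the reverse, so part of the treatment difference stays between the groups and the rest widens the spread within them, and the counts are no rate of chance calls.

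The first pattern was that inflammatory genes rose beside antiviral ones, with medians of 2.35 and 2.52. A single donor's response does not account for it, since the lowest donor median was 2.07, and scaling does not either, since the lowest median under quantile normalization and median centring was 2.31. A second stimulus acting through NF-kB in the treated wells, such as a microbial product in the interferon preparation, would also raise other NF-kB-induced genes. In a second list of such genes, 11 of 17 rose with a median of 1.00, as TNIP1 (2.47 ± 0.23) and PDE4B (3.02 ± 0.29) did. IFNalpha itself may do the same in these cells, so the 2 explanations cannot be told apart, because no array had IFNalpha with such a stimulus blocked.

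The second pattern was that lymphocyte markers rose. A larger share of T cells in the treated wells would raise T cell receptor genes and the T cell kinase LCK by as much as IL7R and CCR7. The highest upper 95% bound among CD3D, TRBC1 and LCK was 1.41, while the lower bounds of IL7R and CCR7 were 3.93 and 4.24. CD3E and CD3G were also set out for this comparison but were not among the tested genes. TRBC1, the brightest of the 3, had mean signals of 430 in control and 629 in IFNalpha arrays, and 1 of the list's 20 tested members, CCR7, is also a dendritic cell marker. The bounds argue against a larger share of T cells as the cause for IL7R and CCR7, as far as the signals of CD3D, TRBC1 and LCK were not background. A larger share of NK cells or B cells was not tested. For IL7R and CCR7 induction in the macrophages is a hypothesis. For CD2, CD8A and GZMB the lowest lower bound was 0.81, below that upper bound, so a change in lymphocyte share and induction cannot be told apart.

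The third pattern was the fall of immediate early genes. Of the 32 tested members 10 fell, 7 with quantile normalization and 6 after median centring. The median of these 10 was −3.12, and −3.01 or lower under both other scalings. Scaling does not account for the 6 members that fell past the threshold under all 3 scalings (FOS, FOSB, EGR1, EGR3, NR4A1 and NR4A2). For the other 4, median centring moved the change by 0.11 and ended the calls, from −0.61 ± 0.15 to −0.50 ± 0.15 in JUND, −0.76 ± 0.20 to −0.65 ± 0.20 in DUSP2, −1.75 ± 0.43 to −1.64 ± 0.44 in KLF2 and −0.76 ± 0.19 to −0.65 ± 0.18 in DNAJB1. Their highest upper 95% bound under the other scalings was −0.17, which argues against scaling as the whole cause but not as part of it. Handling that stirred the control wells more would lower such genes in the IFNalpha arrays, and 5 members rose instead (median 1.29; 2 without donor 1 and 3 without control array 1 or 3), but members such as these may rise for another reason. A response to handling and an effect of IFNalpha therefore cannot be told apart, since no array came from cells left without mock treatment.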

How the results depend on the processing

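No named gene with a call, and no list with a camera call at the preset correlation, reversed its direction. Direction was not compared between settings for the other called genes or for calls with an estimated correlation. More genes fell than rose with the donor block, alone or with quantile normalization, while more rose in every other setting. The counts of higher and lower genes were 538 to 600 and 282 to 449 under other pseudocounts, filters, quantile normalization and robust variance, and 682 and 249 after median centring. Without a variance trend 438 rose and 216 fell, with 87 probe sets of no single gene called against 133. Leaving out probe sets that can share sequence gave 434 and 277, the mean of probe sets gave 442 and 234, and testing all probe sets gave 901 and 537 probe sets, a count of another unit. With the donor block the counts were 889, 1098 and 278 (the last for probe sets of no single gene), with quantile normalization added 912, 981 and 268, and with median centring added, chosen after seeing the data, 1041, 631 and 246; the first 2 kept all 958 genes and the third 957. The block removes the spread between donors from the error. Leaving out 1 array gave 424 to 555 higher genes, 181 to 309 lower genes and 81 to 118 probe sets, and leaving out 1 donor gave 280 to 500, 54 to 243 and 41 to 83, where fewer arrays were tested; without donor 2, 332 of the 958 genes were called. The lists past the camera threshold numbered 15 to 20. The cause of the other moves was not tested. Of 113 named genes, 85 were called, 66 of them under all 23 other settings that could give a value; 22 were never called. Over all settings, calls of named genes were kept in 1864 cases, lost in 68 and gained in 21, camera calls of lists kept in 398, lost in 13 and gained in 11, and calls with an estimated correlation kept in 77, lost in 70 and gained in 5. The settings with the block or with arrays left out lower the power of the test with an estimated correlation. The donor block changed no other call of a named gene or of a list in camera or fry, and moved the other counts of list members by at most 1.5 times. Signal over background limits the dim genes: 56 of the 585 higher genes had a control mean under the pooled median signal, so their fold depends on the pseudocount.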

Other observations

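The gene families here were picked after the data were seen, so the counts are descriptive. In 18 families defined by symbol, tested in both directions against the 12627 genes (36 one-sided Fisher's exact tests), the 4 described here passed. Of 12 regulators of G protein signalling, 3 fell (adjusted p = 0.0419): RGS2, RGS18 (−1.90 ± 0.25) and RGS19 (−0.78 ± 0.17). These calls kept their direction and side of the threshold under quantile normalization, median centring and the donor block.

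Members of 3 families were higher more often than other genes. Of 6 metallothioneins, which bind zinc and copper, 3 were higher (adjusted p = 0.0321), with MT2A going from 10297 ± 1867 to 29587 ± 3726, MT1X rising by 1.25 ± 0.23 and MT1G by 1.22 ± 0.29; with the donor block all 6 were. Their probes can share sequence, so they are not independent. Of 8 ligands of the TNF superfamily, 3 were higher (adjusted p = 0.0419): TNFSF10, TNFSF9 (2.44 ± 0.31) and TNFSF13B (1.12 ± 0.18), while 1 fell with the donor block. Of 26 interleukin receptor chains, 5 rose and 1 fell (adjusted p = 0.0442), with IL7R and IL15RA (3.36 ± 0.17) ahead of IL1RAP (2.31 ± 0.30), IL2RA (2.10 ± 0.53) and IL10RA (2.03 ± 0.16), and IL17RA falling by 0.84 ± 0.16; 2 fell with the donor block. Of 33 proteasome subunits 5 rose (adjusted p = 0.102), 2 with quantile normalization. The 358 zinc finger genes tested had 5 higher and 10 lower (25 lower with the donor block), and the 209 solute carriers 7 and 8 (20 lower with the block, 5 after median centring), and neither family passed.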
